A study of Caenorhabditis elegans with 2 samples.

How the data were processed

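Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans animals of both sexes at the L3 larval stage. Per the labels, the strain was OP353, an unc-119(tm4063) mutant with the integrated transgene wgIs353 that carries eGFP-tagged nhr-77, and the description gives the target as the tagged protein. The antibody label names nhr-77 alone, so the antigen of the antibody, the tag or the protein itself, is not settled here. The 2 samples are biological replicates 1 and 2 of 1 group. The series has no second condition among its samples, so no test between groups was made and every comparison is between lists, places or gene groups within this experiment. Where a p-value is given over peaks or genes, it concerns this pair of libraries, because peaks and genes are not replicates.

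The deposited files were peak lists in the narrowPeak layout. Per the labels and the inventory texts deposited with them, the authors called a relaxed list of peaks and background on the alignments of each replicate, and again on both replicates pooled, each against a control. From these 3 relaxed lists they derived a list thresholded by the irreproducible discovery rate (IDR), a procedure based on how alike peaks rank in replicates. A single peak of that list need not rank alike in both replicates, as the recovery counts below show. The lists exist on the assemblies ce11 and ce10, which makes 8 lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' enrichment of the ChIP over the control as their caller wrote it, and its scale differs between lists. It was used only to describe and rank peaks within a list and to correlate matched peaks. The authors' second score is the −log10 of the q-value. It was tied at its maximum for all 590 IDR peaks and was not used to rank them. The read depth of the libraries and the control libraries were not analysed here, so no interval given below covers sequencing depth.

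The IDR list on ce11 was checked to be the 590 highest entries of the pooled relaxed list by signal, and on ce10 the 573 highest. Peaks of the pooled list below that point served as background, since they are places the relaxed calling could return. Coordinates are 1-based on ce11. That assembly has the same sequence as WBcel235, and all ce11 peaks on the nuclear chromosomes were checked to end inside them. Genes, transcripts and biotypes were taken from Ensembl release 115, with 46890 genes on the nuclear chromosomes. Genes without a symbol are given by their sequence name. The ce10 lists were used for list sizes, overlaps and correlations only, as no ce10 annotation was used here.

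Summits within 100 bp counted as the same place. A promoter window reached from 1000 bp upstream to 500 bp downstream of the 5′ end of any annotated transcript, and 1 summit could fall in the windows of several genes. The top 590 peaks of replicate 1 by signal were compared with those of replicate 2, and the overlap was set against 1000 random draws of 590 peaks from the rest of the other replicate's relaxed list (permutation test, one-sided). Signal was correlated over matched peaks with Spearman's rho and with Pearson's r on log2 values, with 100000 permutations (two-sided). Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Shares of peaks, of genes in 30 gene lists and of genes in 8 annotation biotypes were compared with two-sided Fisher's exact tests, with conditional odds ratios and 95% intervals. The background of the gene tests was every gene with a pooled relaxed summit in its promoter window. The lists and biotypes were adjusted together by the Benjamini-Hochberg method, the 8 motifs among themselves, and the location tests among themselves, with a threshold of 0.05. No rRNA gene entered the background, which left 37 lists and biotypes. Motifs were searched on both strands within 100 bp of the summit, with background peaks matched 5 to 1 on GC content in bins of 0.05 and on lying in a promoter window. Summits around the nhr-77 and unc-119 genes were counted within 20 kb on either side.

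The design, the gene lists, the motifs and the rule for named genes were fixed before the data were examined. The rule names nhr-77 and unc-119, the 25 IDR peaks with the highest signal with the genes whose promoter window holds the summit or otherwise the nearest 5′ end, up to 4 members with the highest signal of each list past the threshold or with at least 3 members bound, and at most 2 members of any other list; biotypes were treated as lists. The strongest protein coding genes are among the 25 peaks. Alternatives changed 1 choice at a time. They covered the assembly, the matching distance, the number of peaks, the promoter window, the background, the motif window and matching, and each replicate on its own. Further alternatives, such as leaving out chromosome X, piRNA 5′ ends or mitochondrial peaks, were chosen after seeing the data.

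The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and blastn 2.17.0 for copies of peak sequences. The tests were run on simulated selections from the 30000 pooled peaks before use. With a sampling weight of 10 on ribosomal protein promoters, that list was recovered in 20 of 20 simulations. With no effect planted, 8 of 740 gene list and biotype tests passed the threshold, in 6 of 20 simulations, and 7 of the 8 were biotypes. Several genes can share 1 peak, which the exact test does not account for, so calls of biotypes with small odds ratios are weakly founded. A nuclear receptor motif planted in 30% of peaks was recovered in 20 of 20 simulations, and 0 of 160 motif tests passed with none planted. With 240 shared peaks planted, a median of 240 of 590 were recovered as overlap.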

Results

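The data are ChIP-seq peaks from L3 larvae of C. elegans that carry an eGFP-tagged form of NHR-77, a member of the nuclear hormone receptor family of transcription factors and the labelled target. There were 2 biological replicates of 1 group. On ce11 each replicate and the pool of both had a relaxed list of 30000 entries, and the IDR list held 590 peaks that together covered 0.195 Mb. The median peak width was 344 bp in the pooled and IDR lists, 320 bp in replicate 1 and 270 bp in replicate 2. Exactly the median width was held by 90.5% of IDR peaks and by 99.8 to 99.9% of each relaxed list. Width was thus nearly constant within a list. The authors' signal value ranged from 28.9 to 426.8 in the IDR list with a median of 38.5, against a median of 8.27 over the whole pooled list. On ce10 the IDR list held 573 peaks. The read depth behind the values is unknown.

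The strongest peaks lay on chromosome X. All of the first 13 IDR peaks by signal were X-linked, as were 14 of the first 15 and 17 of the first 25 (68%, 95% interval 46.5 to 85.1%). Of these 17 peaks, 13 had a summit in no promoter window. In each replicate taken alone, 16 of the 25 strongest peaks were on X. The share fell with rank, to 32% of the first 100 and 19.5% (16.4 to 22.9%) of all 590, beside 17.7% of the nuclear genome. Over the whole IDR list, X was not enriched against the other pooled peaks, of which 17.4% were X-linked (odds ratio 1.15, interval 0.924 to 1.41, p = 0.208 by Fisher's exact test, adjusted p = 0.223 over 15 location tests). Among the 295 stronger IDR peaks the odds ratio was 1.47 (p = 0.00686, Fisher's exact test), an alternative chosen after seeing the data.

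**Figure D1:**
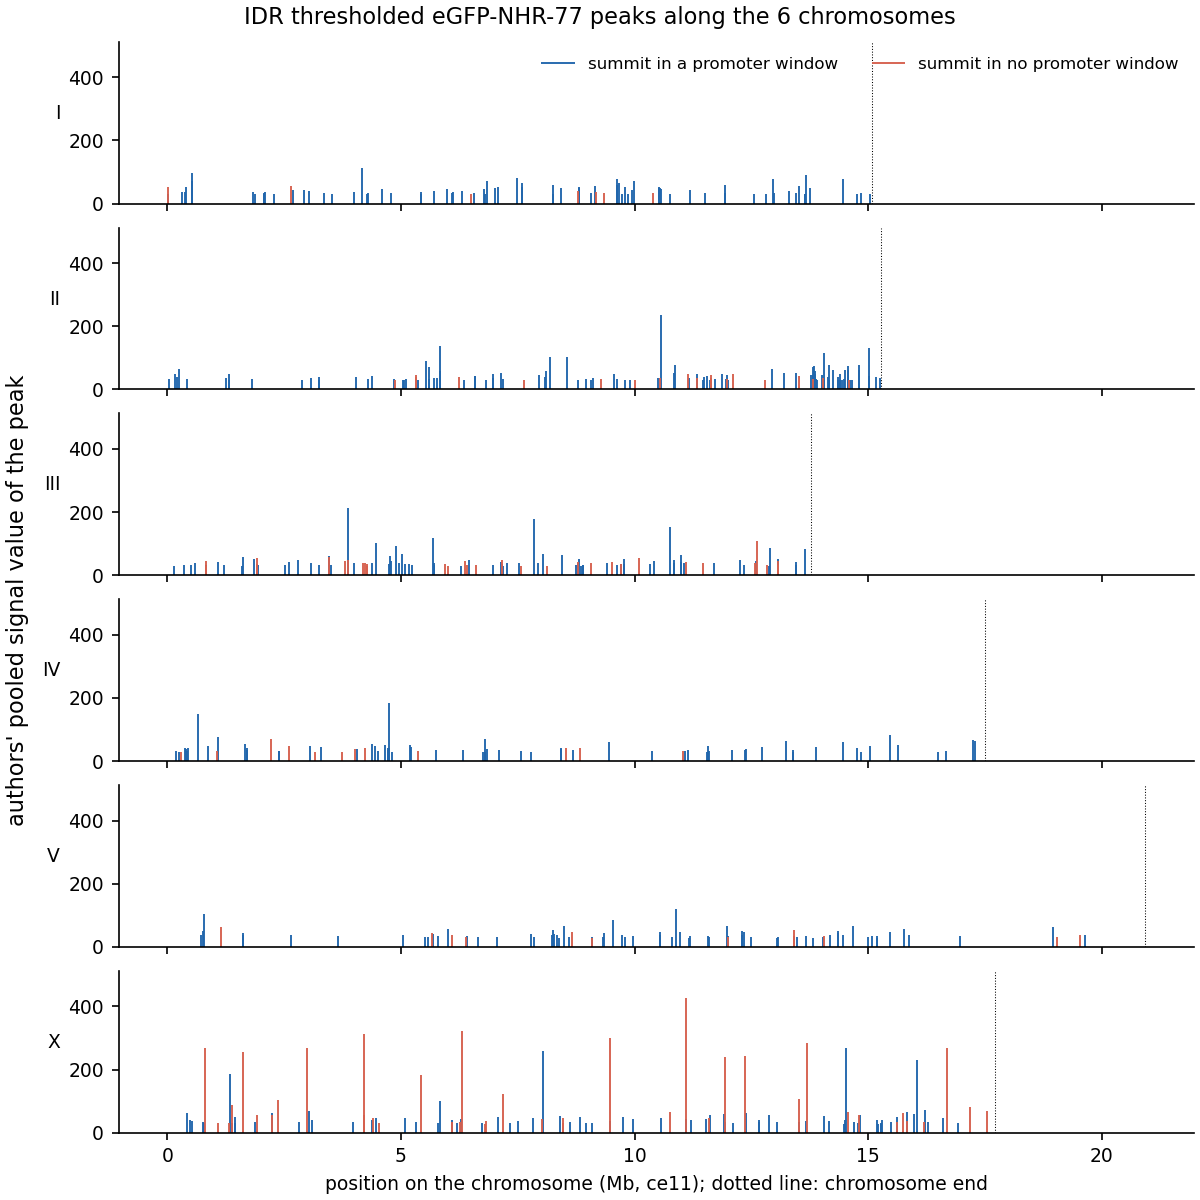
Each vertical line is 1 of the 590 IDR peaks, placed by its summit on ce11 (horizontal axis, Mb) with its height the authors' pooled signal value, blue where the summit lies in a promoter window and red where it does not; dotted lines mark chromosome ends. The tallest lines, up to 426.8, are on X and mostly red, and the tallest autosomal line is at cdc-48.1 on chromosome II.

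The highest signal, 426.8, belonged to an intergenic peak on chromosome X from 11093970 to 11094369, ranked 1 in both replicates, and the nearest annotated 5′ end was that of the tRNA gene W02H3.t1 at 1474 bp. The next was intronic, from 6296338 to 6296769, within the span of mom-1 (6293112 to 6298305), and ranked 3 in both replicates. Its summit lay 3358 bp upstream of the nearest annotated 5′ end, that of cest-16, a carboxylesterase gene. The peak from 4209092 to 4209439 lay 1791 bp upstream of F20B6.9, that from 9465693 to 9466014 lay 1842 bp upstream of the noncoding RNA gene ZK899.10, and that from 13700639 to 13701018 lay 3054 bp upstream of the noncoding RNA gene K02D3.5. An intronic peak from 2996908 to 2997341 was nearest to the piRNA gene 21ur-12946, at 1264 bp. Peaks outside promoter windows were also found at 16681956 to 16682298 and at 806528 to 806859, 2576 bp downstream of the 5′ end of F22H10.2 and 3892 bp downstream of that of gtr-1. Others lay at 1626994 to 1627307, 1006 bp upstream of fbxb-58, at 12362959 to 12363396, 1709 bp downstream of the 5′ end of F19H6.5, and at 11937353 to 11937694, 1395 bp downstream of that of F55G7.5. The peak from 5429410 to 5429689 had its summit in coding sequence, 10007 bp downstream of the nearest 5′ end, that of the noncoding RNA gene C41A3.6. The last of the 13, from 7181667 to 7181879, was intergenic and 3583 bp downstream of the 5′ end of the microRNA gene cel-mir-4811. The remaining X peaks among the 25 had summits in promoter windows. Of these, summits lay 701 bp upstream of nspc-17, 773 bp upstream of the snoRNA gene T27A8.8, and 605 bp upstream of ins-39, an insulin-like peptide gene (chromosome X, 1344877 to 1345195, signal 185). The other summit lay 236 bp upstream of the noncoding RNA gene C18A11.13. It was also 319 bp downstream of the 5′ end of the tRNA gene C18A11.t2, past the 3′ end of that gene.

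The 8 autosomal peaks among the 25 strongest all had summits in promoter windows of protein coding genes, and 4 of them at ribosomal protein genes. The first, from 10563446 to 10563702 on chromosome II and ranked 14 in the pool, lay 177 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control, and also upstream of the snoRNA gene C06A1.9. The ribosomal protein promoters were those of rpl-3 (chromosome III, 3867443 to 3867698, signal 212), rpl-20 (IV, 4749977 to 4750188, signal 183, shared with Y17G9B.5), rpl-35 (III, 7854572 to 7854810, signal 178) and rpl-15 (IV, 654822 to 655035, signal 148, shared with K11H12.8 and the snoRNA genes K11H12.12 and K11H12.13). Their summits lay 260, 286, 455 and 350 bp upstream of the 5′ ends. The others were at tasp-1 and K01G5.10 (III, 10759131 to 10759363), at the spliced leader RNA gene sls-2.1 and H41C03.3 (II, 5844766 to 5844968), and at cmtr-1, a cap methyltransferase gene, with the snoRNA gene Y53F4B.47 (II, 15025869 to 15026066). Of the 25 peaks, 24 were within the first 50 of both replicates. The exception was the sls-2.1 peak, ranked 49 in replicate 2 and with no summit within 100 bp in the list of replicate 1. A neighbouring IDR peak in the same promoter window (II, 5844876 to 5845219), chosen after its values were seen, was matched in replicate 1 at rank 21 with a signal of 79.5 and had no match in replicate 2.

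The replicates ranked many of the same places high. Of the top 590 peaks of replicate 1, 263 (44.6%, 95% interval 40.5 to 48.7%) had a summit within 100 bp of a top 590 peak of replicate 2, and the reverse count was also 263. Random draws from the rest of the list of replicate 2 gave a mean of 3.63 and at most 11 (permutation test, one-sided, p = 0.000999, the smallest that 1000 draws can give). The shared part was 72% of the first 25, 53% of the first 100 and 13.8% of all 30000. Of the 590 IDR peaks, 69.7% (65.8 to 73.3%) were found in the top 590 of replicate 1, 64.2% (60.2 to 68.1%) in that of replicate 2, and 266 in both. IDR peaks are the strongest of both replicates pooled, so part of this recovery follows by construction. A total of 66 were in neither top list, although only 2 of the 590 were in neither relaxed list.

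**Figure D2:**
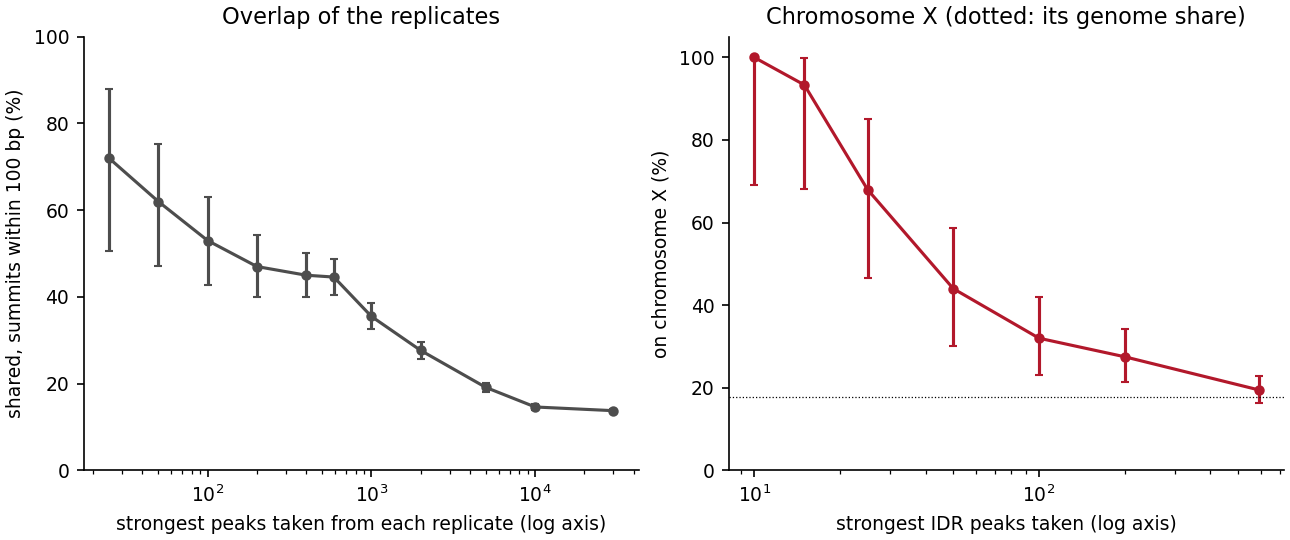
Left, the share of the strongest peaks of replicate 1 found among as many of replicate 2 (vertical axis, percent) against the number taken (log axis); right, the share of the strongest IDR peaks on chromosome X (percent) against the number taken (log axis). Bars are exact 95% intervals; the overlap runs from 72% of 25 to 13.8% of 30000, and the X share from 100% of 10 to 19.5% of 590 with 17.7% of the genome as the dotted line.

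Signal was correlated between replicates across the 524 IDR peaks matched in both (rho = 0.337, r = 0.54 on log2 signal, two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted p = 1e-05 over 8 relations). Without the 2 peaks farthest from the median of replicate 1, r was 0.51. Over all 4183 matched pooled peaks rho was 0.441 and r 0.61 (permutation p = 1e-05). Across the 99 matched X peaks rho was 0.663, and across the 425 autosomal ones 0.239 (permutation p = 1e-05 for each); the difference was not tested. In the stronger 295 IDR peaks, 275 of them matched, rho was 0.365, and in the weaker 295, 249 of them matched, it was negative at -0.511 (permutation p = 1e-05 for each). These correlations are across peaks, which were chosen by their pooled signal and are not independent. The permutation p-values do not account for that choice.

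**Figure D3:**
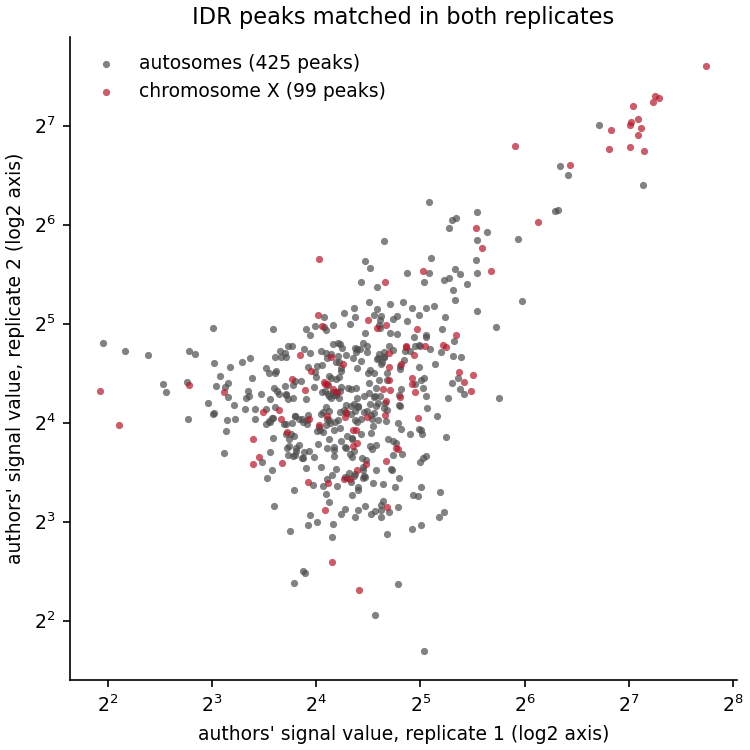
Each point is 1 of the 524 IDR peaks matched in both replicates, with the authors' signal value in replicate 1 (horizontal) and replicate 2 (vertical), both on log2 axes; red points are the 99 peaks on X and grey points the 425 on autosomes. Peaks of the highest signal in both replicates are mostly red, and the bulk of weaker peaks forms a cloud.

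IDR peaks lay in promoter windows more often than other pooled peaks. The summit lay in a promoter window for 468 of 590 IDR peaks (79.3%) and for 49.6% of the 29410 other pooled peaks, an odds ratio of 3.89 (3.18 to 4.80, two-sided p = 5.51e-49 by Fisher's exact test). The odds ratio was 3.59 with replicate 1 alone and 2.87 with replicate 2 alone. In the latter, 21 mitochondrial peaks among the top 590 counted as outside promoter windows. The promoter share was 82.7% on autosomes and 65.2% on X. The median summit was 163 bp upstream of the nearest protein coding 5′ end on autosomes, where 73.1% of summits were upstream of it and the median absolute distance was 328 bp. On X 60% were upstream and the median absolute distance was 1315 bp, beside 1123.5 bp for the other pooled peaks of all chromosomes. By annotation of the summit itself, coding sequence held 4.41% of IDR peaks against 21.1% of the others and introns 11.5% against 35.2%. Intergenic sequence held 63.9% against 33.2%, noncoding exons 13.6% against 3.36%, 5′ UTRs 3.90% against 1.89% and 3′ UTRs 2.71% against 5.27%. Each of these 6 differences passed the threshold (Fisher's exact test, adjusted p at most 0.00606). Among autosomes the largest share of IDR peaks was on chromosome II, with 20.3% against 16.5% of the other peaks (odds ratio 1.29, adjusted p = 0.0219, Fisher's exact test). Shares on IV (13.2% against 16.5%, adjusted p = 0.0412) and V (13.7% against 17.6%, adjusted p = 0.0207) were lower by the same Fisher's exact test. Chromosomes I (14.4% against 15.9%) and III (18.8% against 16%) did not pass the threshold.

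Among the gene lists, ribosomal proteins, heat shock proteins, translation factors and oxidative phosphorylation genes were bound more often than other genes. IDR summits lay in the promoter windows of 863 genes out of 18626 with any pooled summit there. The cytosolic ribosomal proteins had 32 of 78 members bound (41%, against 4.48% of other genes), through 30 distinct peaks, an odds ratio of 14.8 (9.08 to 23.9, adjusted p = 2.20e-21, Fisher's exact test), and 11.4 and 14.3 with replicate 1 or 2 alone. Its members with the highest signal were rpl-3, rpl-20, rpl-35 and rpl-15. Translation factors had 9 of 37 bound (odds ratio 6.67, 2.76 to 14.6, adjusted p = 0.000192, Fisher's exact test), led by iff-2, which encodes initiation factor eIF5A, with a signal of 103 and a summit 41 bp upstream, and by ifet-1 (102), eif-3.C (71.4) and eif-3.B (62.8). The ifet-1 summit (480 bp upstream) was also 288 bp upstream of rps-1, a ribosomal protein gene named after its value was seen. Oxidative phosphorylation genes had 9 of 39 bound (6.23, 2.59 to 13.5, adjusted p = 0.000264, Fisher's exact test), among them the cytochrome c oxidase genes cox-5A (85.5), cox-5B (54) and cox-6B (48.5) and the ATP synthase gene asb-2 (46.6). Heat shock proteins had 9 of 36 bound (6.92, 2.85 to 15.2, adjusted p = 0.000177, Fisher's exact test), including the chaperone genes hsp-90 (67.1), hsp-1 (63.5), hsp-110 (62.9) and hsp-60 (57.4). All 4 lists passed with either replicate alone. When each summit was given only to the gene with the nearest 5′ end, oxidative phosphorylation and heat shock proteins no longer passed (adjusted p = 0.0935 and 0.349, Fisher's exact test). Their odds ratios were then 4.48 (1.12 to 13.3) and 2.83 (0.547 to 9.30).

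Chemoreceptor genes were bound less often than other genes, with 4 of 283 (1.41% against 4.68%, odds ratio 0.292, 0.0788 to 0.758, adjusted p = 0.0216, Fisher's exact test). The 4 were sri-5, srh-16, srz-97 and sre-23, with signals of 44, 39.2, 36.4 and 30.5. The odds ratio was below 1 with either replicate alone (0.129 and 0.338). The list missed the threshold with the narrower window of 500 bp on either side, with the stronger 295 IDR peaks and with the nearest gene alone (odds ratios 0.299, 0.285 and 0.205, adjusted p = 0.0913, 0.249 and 0.0605, Fisher's exact test).

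The remaining 25 lists did not pass the threshold (Fisher's exact test, adjusted p from 0.0936 to 1). With all annotated genes as background, proteasome and V-ATPase subunits passed (odds ratios 7.39 and 8.92, adjusted p = 0.00966 and 0.0189, Fisher's exact test). That background also moved the odds ratios of ribosomal proteins to 36.1, translation factors to 15.1, oxidative phosphorylation to 12.8, heat shock proteins to 11, snoRNA genes to 12.2, tRNA genes to 5.91, chemoreceptors to 0.159 and pseudogenes to 0.145. Leaving out piRNA 5′ ends, a setting chosen after seeing the data, lowered all of these odds ratios from those of the main background, and each still passed. They were then 11.2 for ribosomal proteins, 5.02 for translation factors, 4.69 for oxidative phosphorylation and 5.21 for heat shock proteins. For snoRNA genes the value was 5.75, and for tRNA genes 2.35. Fatty acid metabolism passed as lower in that setting (adjusted p = 0.0483, Fisher's exact test). Nuclear hormone receptor genes had 5 of 131 bound (3.82%), namely nhr-238 (signal 45.5), nhr-237 (36.8), nhr-142 (36), nhr-68 (33.8) and, named after its value was seen, nhr-47 (32). Proteasome subunits had 4 of 26, namely rpn-3, pas-5, rpn-11 and pbs-1, and the rpn-3 summit was the one at hsp-110. V-ATPase subunits had 3 of 18 (vha-8, vha-1 and vha-2), and histones 4 of 27 (his-37, his-42, htz-1 and his-24). The bHLH and bZIP factors had 4 of 33 (jun-1, cebp-1, hlh-11 and zip-2), and this list passed with replicate 1 alone (odds ratio 4.55, adjusted p = 0.0234, Fisher's exact test) but had an odds ratio of 0.829 with replicate 2 alone. The list of pharynx markers, filled by gene symbol, had 4 of 40, all of them pqn genes (pqn-27, pqn-71, pqn-51 and pqn-59). Whether these 4 are expressed in the pharynx was not examined. F-box and MATH genes had 5 of 94, namely fbxb-85, fbxb-72, fbxa-90, fbxc-19 and, named after its value was seen, bath-36. A single member was bound among cuticle collagens (col-63, of 84), molting genes (myrf-1, of 16), heterochronic genes (lin-66, of 10), cytochrome P450s (cyp-13A2, of 32) and UGTs and GSTs (gst-27, of 59). The same held for C-type lectins (clec-57, of 54), neuron markers (snb-1, of 51), epidermis and seam markers (ajm-1, of 17), Wnt and Notch pathways (mom-1, of 20) and insulin and TGF-beta pathways (ins-39, of 35). No member was bound among 41 homeobox genes, 13 GATA and T-box factors, 37 hedgehog-related and patched-related genes, 75 fatty acid metabolism genes, 2 vitellogenins, 34 intestine markers, 23 muscle markers and 17 germline markers in the background.

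**Figure D4:**
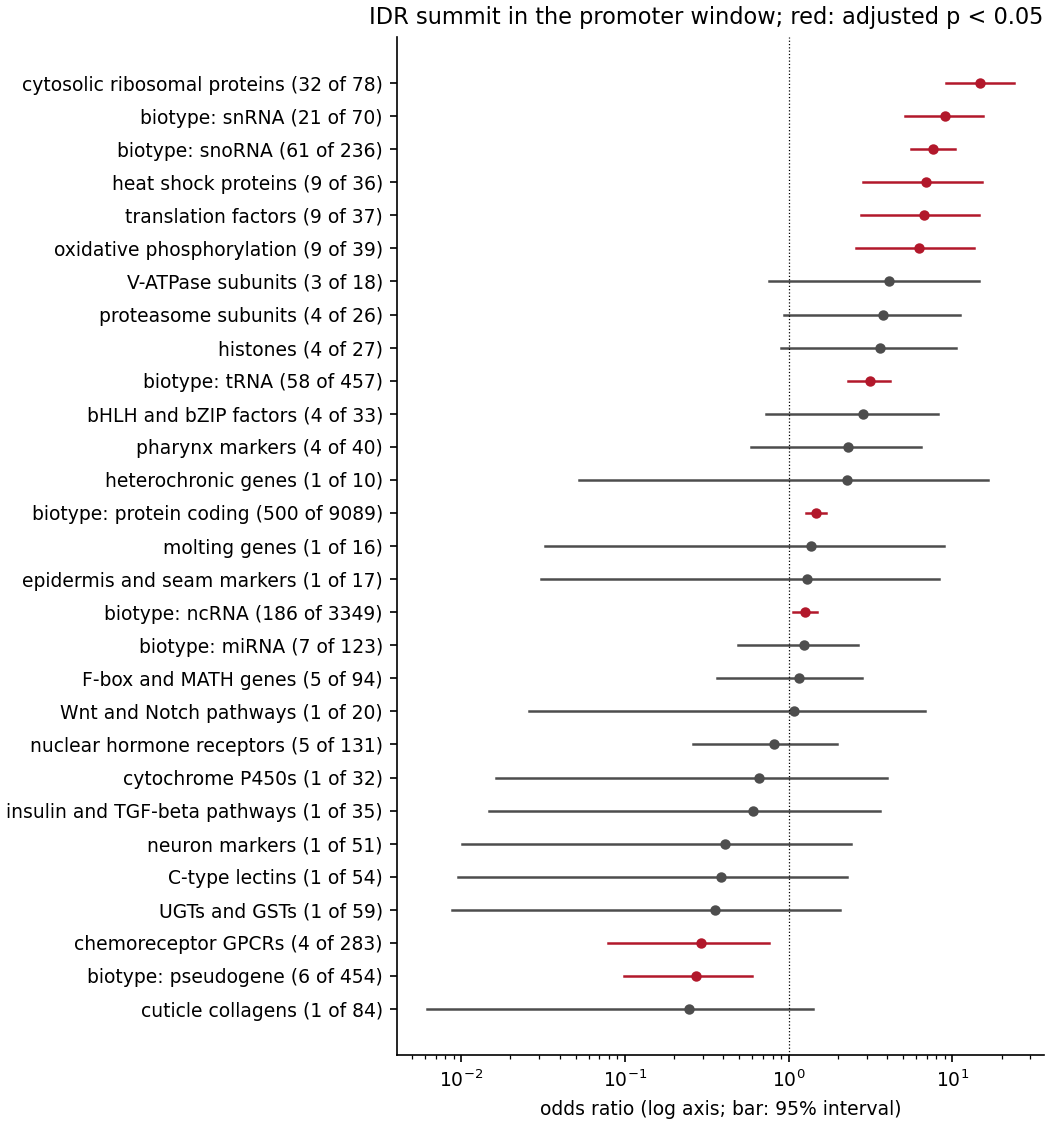
Odds ratio (points, log axis) with its 95% interval (bars) for an IDR summit in the promoter window, for each list and biotype with at least 1 bound gene; numbers give bound genes out of those in the background, and red marks an adjusted p below 0.05. Ribosomal proteins (14.8), snRNA (9.01) and snoRNA (7.64) genes are highest, and chemoreceptors (0.292) and pseudogenes (0.271) are low.

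Genes of small structural RNAs were also bound often. Of the snoRNA genes 61 of 236 were bound (25.8%, odds ratio 7.64, 5.57 to 10.4, adjusted p = 2.08e-27, Fisher's exact test), led by C06A1.9, T27A8.8 and the pair K11H12.12 and K11H12.13. C06A1.9 lies within cdc-48.1 and the pair within rpl-15, and their summits were nearer to the 5′ ends of these host genes. The distances were 177 bp to cdc-48.1 against 520 bp to C06A1.9, and 350 bp to rpl-15 against 896 and 565 bp to the pair. Of the snRNA genes 21 of 70 were bound (30%, odds ratio 9.01, 5.11 to 15.4, adjusted p = 3.13e-11, Fisher's exact test). The strongest were the spliced leader genes sls-2.1 (138), sls-2.4 (111) and sls-2.2 (90.6), followed by C47F8.9 (71.6). Of the tRNA genes 58 of 457 were bound through 42 peaks (12.7%, odds ratio 3.14, 2.32 to 4.18, adjusted p = 3.13e-11, Fisher's exact test), led by C18A11.t2 (258) and by R11.t1, R11.t2 and R11.t3, which share a peak of 72.4. The C18A11.t2 summit lay 319 bp downstream of its 5′ end, past the end of the gene. With chromosome X left out, chosen after seeing the data, the tRNA odds ratio was 1.47 and no longer passed (adjusted p = 0.319, Fisher's exact test). In a comparison also chosen after seeing the data, of the tRNA genes on X 19.2% were bound and of those on autosomes 6.44% (odds ratio 3.44, 1.81 to 6.90, unadjusted p = 3.86e-05, Fisher's exact test). All 3 classes passed with either replicate alone, and the snoRNA odds ratio was 4.96 with replicate 2 alone.

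Pseudogenes were bound less often, with 6 of 454 (1.32%, odds ratio 0.271, adjusted p = 0.000652, Fisher's exact test), led by C01B9.5 (44.7), K08F11.6 (42.6), T07A9.1 (41.5) and F21F8.6 (40.1). The odds ratio was 0.329 with replicate 1 and 0.180 with replicate 2 alone. They missed the threshold with the narrower window, with the stronger 295 peaks and with the nearest gene alone (adjusted p = 0.0532, 0.106 and 0.153, Fisher's exact test). Among miRNA genes 7 were bound (5.69%, odds ratio 1.24, adjusted p = 0.757, Fisher's exact test), led by cel-mir-354, cel-mir-1824, mir-2214 and cel-mir-4936. The biotype passed with replicate 1 alone (odds ratio 2.60, adjusted p = 0.00938, Fisher's exact test). With replicate 2 alone it did not (odds ratio 2.14, 0.996 to 4.11, adjusted p = 0.0848, Fisher's exact test). Among other ncRNA genes 186 of 3349 were bound (odds ratio 1.27, adjusted p = 0.0216, Fisher's exact test), led by C18A11.13, R12E2.18, F56F3.11 and F56F3.10. Protein coding genes as a class had 500 of 9089 bound (odds ratio 1.47, adjusted p = 3.01e-07, Fisher's exact test). Genes that share a peak are counted separately, so these p-values are too small, and on simulated data with no effect biotypes were called by chance. Without piRNA 5′ ends, chosen after seeing the data, the odds ratio was 0.887 for ncRNA genes (adjusted p = 0.344, Fisher's exact test) and 0.760 for protein coding genes (adjusted p = 0.00104, Fisher's exact test). With the nearest gene alone the odds ratios were 1.02 and 0.852 (adjusted p = 1 and 0.349, Fisher's exact test), and ncRNA genes also missed the threshold with replicate 2 alone, with 2000 bp upstream and with the stronger 295 peaks (adjusted p = 0.0763, 0.169 and 0.733, Fisher's exact test).

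Motif matches around IDR summits differed from matched peaks for 2 of the 8 sequences searched. GAGAGA was present in 32.9% of 589 IDR peaks and 21.1% of 2945 matched peaks (odds ratio 1.84, 1.51 to 2.24, adjusted p = 1.30e-08, Fisher's exact test). The C/EBP-type site TTGCGCAA, with at most 1 mismatch, was present in 17% against 9.37% (1.98, 1.53 to 2.55, adjusted p = 9.46e-07, Fisher's exact test). Both passed with either replicate alone and without chromosome X. The nuclear receptor motif sequences AGGTCA (5.43% against 6.42%) and AGTTCA (9.34% against 10.7%) and the HNF4-type site CAAAGTCCA (3.23% against 4.96%) were not enriched. Their odds ratios were 0.838 (0.551 to 1.24), 0.857 (0.622 to 1.16) and 0.639 (0.371 to 1.04), with adjusted p = 0.532, 0.532 and 0.185 by Fisher's exact test. Within 250 bp AGGTCA was less frequent in IDR peaks (odds ratio 0.626, adjusted p = 0.00434, Fisher's exact test), and in the stronger 295 peaks AGTTCA was less frequent (0.479, adjusted p = 0.00882, Fisher's exact test). TGATAA (12.9% against 14.8%), CACGTG (5.60% against 5.06%) and CAGCTG (5.77% against 6.69%) did not pass either (adjusted p = 0.497, 0.609 and 0.532, Fisher's exact test). Without matching, the odds ratio of GAGAGA was 3.14, CACGTG passed as more frequent (1.56), and AGTTCA (0.710) and TGATAA (0.664) passed as less frequent (adjusted p = 0.0322, 0.0288 and 0.00174 for these 3, Fisher's exact test).

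No IDR peak lay within 20 kb of either locus tied to the transgene, as for 77.6% of protein coding genes on the chromosome of nhr-77 and 70% on that of unc-119. Around nhr-77 itself (WBGene00003667, chromosome I, 12384277 to 12385731, minus strand) there were 4 pooled relaxed summits against a median of 14 over the 2878 protein coding genes of the chromosome, of which 3.27% had as many or fewer. That share was 14.1% within 10 kb, 7.37% within 40 kb, 6.18% with replicate 1 alone and 3.96% with replicate 2 alone. The strongest of the 4 ranked 14798, with a signal of 8.32. The nearest IDR summit was 165511 bp away. Around unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand) there were 13 relaxed summits against a median of 15, and 37.2% of 2640 genes had as many or fewer, a share of 65.8% with replicate 1 alone and 67.2% with replicate 2 alone. The strongest ranked 5890 with a signal of 12.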

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

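Leaving out mitochondrial peaks was chosen after the result was seen. The relaxed list of replicate 2 held 24 peaks on the mitochondrial genome. Those of replicate 1 and of the pool held 0 among 30000 entries each, a count that allows up to 3. The mitochondrial peaks entered the ranking of replicate 2, and so the promoter and gene comparisons with replicate 2 alone. There they counted as outside promoter windows and added no gene. No promoter or gene comparison of the pooled list contained them. Of the 24 peaks, 21 were among the top 590 of replicate 2, the best at rank 2 with a signal of 166. Their median signal was 54.4. With them left out, the share of the top peaks of replicate 1 found in replicate 2 was 44.7% and the share of IDR peaks found in the top list of replicate 2 was 65.1%. No explanation was tested.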

How the results depend on the processing

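The alternatives run kept the direction and the call of the replicate overlap (32 to 50.2%, permutation p = 0.000999 throughout) and of the promoter excess (odds ratio 2.85 to 4.79). Settings that took the weaker peaks or protein coding 5′ ends alone, or left out piRNA 5′ ends, chromosome X or mitochondrial peaks, were chosen after seeing the data. The rank correlation of signal between replicates reversed to -0.511 in the weaker IDR peaks, which span a narrow range of the pooled signal they were chosen by. Such a choice can by itself lower the correlation, and how much of the reversal it explains was not tested. The share of IDR peaks found in replicate 1 moved to 61.5% within 50 bp, 46.4% with N divided by 2 and 83.4% with 2 times N. In replicate 2 it moved to 55.9, 40.2 and 77.5%, and to 69% both within 250 bp and with any interval overlap; stricter or looser matching gives these by construction. Called gene lists rose from 5 to 8 with 2000 bp upstream (V-ATPase, histones and pharynx markers added) and fell to 2 with the nearest gene alone, where called biotypes fell from 6 to 3; the cause was not tested. Without matching, 5 motifs passed instead of 2. The share of genes with as few relaxed summits as nhr-77 was 14.1% at 10 kb and 7.37% at 40 kb, and 3.96 to 6.18% with 1 replicate. That of unc-119 was 52.5% at 10 kb and 28.1% at 40 kb, and 65.8 to 67.2% with 1 replicate. Odds ratios reversed for protein coding genes (0.760 without piRNA 5′ ends, 0.852 with the nearest gene), ncRNA genes (0.887 without piRNA 5′ ends), miRNA genes (0.681 in the stronger peaks, 0.935 without piRNA 5′ ends), bHLH and bZIP factors (0 in the stronger peaks, 0.829 to 4.55 with 1 replicate), CACGTG (0.888 at 250 bp) and AGGTCA (1.10 without matching, 1.34 in the stronger peaks, 1.01 to 1.05 with 1 replicate); the cause was not tested. Of 173 comparisons of lists and biotypes, 145 kept direction and call. The 25 strongest peaks were in the top 590 of each replicate in 49 cases, with no match within 100 bp for the sls-2.1 peak in replicate 1, where a neighbouring peak ranked 21. No paired analysis was possible because there is 1 group. The depth of the libraries is unknown.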

Other observations

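The tests of 8-base words, of the 12-base element, of broadly used against tissue genes, of the sls-2 genes and of the flanks of nhr-77 were chosen after the results they concern had been seen. Word counts around summits gave sequences that the 8 fixed motifs did not include. All 8-base words were compared between IDR peaks and relaxed peaks of the same chromosomes matched on GC content and promoter window, by a one-sided exact hypergeometric test. On autosomes the first of 32830 words was CTGGCGCA, in 27 of 475 IDR peaks (5.68%) and 6 of 2375 matched peaks (0.253%), adjusted p = 6.99e-12 by that exact test. It was followed by AGACGCAG, in 14.5% against 4.17% (adjusted p = 1.08e-10, exact test). On X, over the 40 IDR peaks outside promoter windows, 9 of 20562 words passed. CGCAGGGA was in 13 of the 40 and 0 of 200 matched X peaks (adjusted p = 2.45e-07, exact test), GCGCAGGG in 12 and 0 (adjusted p = 9.96e-07, exact test), and GCGAAGGG in 11 and 0 (adjusted p = 5.24e-06, exact test).

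Of these 3 words on X, CGCAGGGA and GCGCAGGG lie within TCGCGCAGGGAG, known as the element enriched at sites that recruit the dosage compensation complex to the X chromosomes of hermaphrodites, and a hypothesis is that the strong X peaks outside promoter windows coincide with such sites. Matches with at most 1 mismatch occurred in 20% of these 40 peaks (8) and in 0 of 200 matched X peaks. They also occurred in 3 of the 75 X IDR peaks in promoter windows and in 0 of 475 autosomal IDR peaks. Among the 25 strongest, 10 of the 17 X peaks had a match, not all of them outside promoter windows. Of 32 such matches on X 15 had an IDR summit within 100 bp, and of 37 on autosomes 0; the element was taken up after matches in these same peaks had been seen, so these counts describe the peaks and do not test the hypothesis. Second copies of the 201 bp around the summit were sought at 90% identity over at least 80% of that length. They were found for 0 of the 40 peaks (0%, 95% interval up to 8.81%). This argues against repeated sequence of that length, and shorter repeats were not examined. GC content as the whole cause is also argued against. X held 32.8% of IDR peaks outside promoter windows and 19.2% of GC-matched ones (odds ratio 2.05, 1.30 to 3.21). Whether the tagged protein, or any immunoprecipitation from this chromatin, gives these peaks stays open, because lists of other proteins and of untagged worms were not used here; with 1 group, no biological explanation was tested for this or the next 2 patterns.

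Ribosomal protein promoters kept their excess against background peaks matched on GC content, with an odds ratio of 9.19 (4.74 to 18.7), which argues against GC content as the whole cause. The peaks may instead follow promoters that are active in most cells. Of the genes in 6 lists of broadly used genes (ribosomal proteins, translation factors, proteasome, V-ATPase, oxidative phosphorylation and heat shock proteins) 28.2% were bound, and of those in the 6 tissue marker lists 3.31% (66 of 234 against 6 of 181, odds ratio 11.4, 4.79 to 33.1). With the ribosomal proteins themselves left out, 34 of 156 (21.8%) were bound (odds ratio 8.08, 3.22 to 24.3). Of the 6 bound tissue genes, 4 were the pqn genes of the pharynx list, whose expression was not examined. These groups were put together after the results of their lists had been seen, so the contrast restates those results and is no test, and with no measure of promoter activity used here this explanation cannot be told apart from binding directed at these genes.

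For the small RNA genes, peaks with shared sequence and peaks in shared promoters were left out in turn. A second copy had to span at least 80% of the 201 bp around the summit. A copy of a shorter gene alone, such as the tRNA gene C18A11.t2 (8036685 to 8036757), could not register. Second copies were found for 1 of 56 IDR peaks at snoRNA genes, 3 of 22 at snRNA genes and 0 of 42 at tRNA genes. After peaks with a second copy were left out, the odds ratios were 7.44 for snoRNA, 9.63 for snRNA and 3.20 for tRNA genes. Of the same IDR peaks, 26, 15 and 10 also lay in a protein coding promoter window. With such peaks left out, the odds ratios were 12.8 (8.01 to 19.9), 9.93 (3.90 to 22.4) and 7.24 (4.91 to 10.5). The bound shares were then 21.4, 19.5 and 12.7%, against 25.8, 30 and 12.7% before. The shares of the other genes fell from 4.36, 4.54 and 4.43% to 2.08, 2.38 and 1.97%, so the higher odds ratios came from the comparison genes. Windows shared with protein coding promoters are argued against as the whole cause for each of the 3 classes. Shared sequence cannot be decided, because the filter could not register copies of short genes and removed few or none of these peaks. What else these genes share was not tested. Of the 18 annotated sls-2 genes, which encode the SL2 spliced leader RNA of operon transcripts, 17 were in the background and 9 were bound.

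Relaxed summits were also counted farther from nhr-77. Between 20 and 40 kb there were 10 pooled summits against a chromosome median of 12, with 33.1% of protein coding genes having as many or fewer, and each replicate had 12. Between 40 and 100 kb there were 13 pooled summits against a median of 38, with 0.903% of genes having as many or fewer. In that range replicate 1 had 26 (10.1% of genes) and replicate 2 had 19 (2.08%), each against a median of 38.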
